A study of Mus musculus with 2 samples.

How the data were processed

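Small RNA of the size class of microRNAs was sequenced from 2 biological replicates of mixed-sex mouse hearts at embryonic day 12.5, 1 library each. Per the labels and the descriptions deposited with the tables, the assembly was mm10 and the annotation M4, which was read as the GENCODE release of that name. The deposited values are raw counts of reads per microRNA gene, with 1 table per library and no pooling. The aligner and counter are not given in the sources used here. Each table holds 3 columns of counts, without regard to strand, on the gene's strand and on the opposite strand. The columns have no names, so their meaning was inferred from the values: with the rows that name no gene, all 3 sum to the same total within a library, and 1 holds nearly all counts of the column without strand. That column was taken as the sense counts and used for the results.

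Each table opens with 4 rows that name no gene, and these were kept out of library sizes and tests. Reads that fit several places made up 27.1% and 25.3% of all reads in replicates 1 and 2, unmapped reads 18.1% and 19.1%, and reads outside microRNA genes, by the sense column, 6.29% and 5.88%. Ambiguous reads numbered 0. Reads that fit several places are in no gene's count, so genes with near-identical copies are measured through their distinguishing reads alone. Antisense counts made up 4.62% and 4.15% of the counts without regard to strand.

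Names and positions came from GENCODE M21 on GRCm38, the assembly also called mm10. Of 1973 gene rows, 1894 had an identifier in that release. The 79 others held 1 count in replicate 1 and 0 in replicate 2. Members of lists were also matched through the synonyms of a RefSeq gene table of GRCm38.p6, by which Mirlet7j and Mirlet7k were found as Mir7j and Mir7k, and Mir146a as Mir146. Hairpins were compared by 22-base windows taken from the M21 transcripts.

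CPM was computed over the sum of sense counts of all genes. A pseudocount of 1 was added before log2, and genes had to reach 10 CPM or, for comparisons of libraries, 10 counts in total where stated. Scaling between libraries used TMM from edgeR 4.0.16 in R 4.3.3, which also gave the common dispersion, with a bootstrap of 50 draws over genes. An edgeR exact test with that dispersion was an alternative, and its p-values are not given, because each side holds 1 library and the dispersion came from the same 2 libraries. DESeq2 1.42.0 served as an alternative. The exact binomial test compared the 2 counts of each gene given their sum, with Benjamini-Hochberg adjustment over 712 genes, an adjusted p of 0.05 and an absolute log2 ratio of at least 1. Differences are coded as replicate 2 minus replicate 1. Permutation tests used 100000 resamples, and random lists and reassignments of cluster members numbered 10000. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.

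The 15 gene lists, the 38 clusters, the tests and the rule for named genes were fixed before the data were examined. The rule took the 20 most abundant genes, every member of the heart and skeletal muscle list and the 2 highest members of each other list. It also took the 5 largest ratios in each direction among genes of at least 50 CPM that passed the binomial test, and the highest and lowest member of each cluster described. Ratios between pairs of genes, and genes outside this rule, were chosen after the values were seen.

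The tests were run on simulated data first. For the comparison of libraries, counts of 712 genes were drawn with 200 genes changed and with counting error alone. This run therefore does not show how often unchanged genes are called when replicates also vary. Among changed genes with at least 100 counts, 36 of 37 with a 2.5-fold and 36 of 36 with a 4-fold change were called, against 51 of 101 and 57 of 99 at any depth, and 1 of 512 unchanged genes. The dispersion step, on 444 genes, returned 0.104 for a set value of 0.1 and 0.308 for 0.3. The tests of copies, copies within clusters and cluster spread passed 0.05 in 18, 22 and 17 of 400 runs without an effect. With an effect, they passed in 374, 304 and 400 of 400 runs, on 200, 36 and 45 simulated genes. The effect was a shift of 3 log2 units for both tests of copies. For cluster spread, the simulated spread within clusters was far below that between them. The simulated values were normal, and gene numbers differed from the data. These runs therefore do not give the power of the tests on the real counts.

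Alternatives changed the strand column, denominator, scaling, pseudocount, filters, test and definition of copies, and left out each replicate in turn. With 1 group, no test between conditions could be made, and with 2 libraries no test of single outlying libraries was made. No genome sequence was used here.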

Results

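MicroRNA-sized RNA was sequenced from whole mouse heart at embryonic day 12.5, the stage at which the chambers are being partitioned. The embryos were of the C57BL/6-derived strain B6NCrl, and both sexes were pooled. All samples formed 1 group of 2 biological replicates, so the design gave no contrast between conditions, and the questions were which microRNA genes the tissue held and how well the 2 libraries matched. Replicate 1 held 9235580 reads, of which 4478599 (48.5%) were counted on the annotated strand of a microRNA gene. Replicate 2 held 10601121 reads, of which 5279908 (49.8%) were so counted. Levels are given as CPM, counts scaled to the sum of these sense counts, as mean ± SD with n = 2. A count of 0 allowed a level of up to 0.670 CPM in replicate 1 and 0.568 CPM in replicate 2. Intervals and limits cover counting error only, because no molecular identifiers are stated for these reads.

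A small set of microRNA genes made up most of the heart's sense counts. Reads that fit several places are in no gene's count, so genes with near-identical copies can stand too low in this ranking. Such reads numbered 0.559 and 0.507 per sense count in replicates 1 and 2. Reads on the strand opposite to a gene are also left out, such as those at Gm25301, where Mir378a is annotated, at 31521 CPM. Mir335, which lies in an intron of the imprinted gene Mest, took 12.3% ± 0.586 (SD, n = 2) of the counts. It was followed by Mir143, known from smooth muscle and its precursors, at 8.84% ± 0.110 (SD, n = 2), by Mir322 at 8.23% ± 0.838 (SD, n = 2) and by Mir99a at 7.32% ± 0.122 (SD, n = 2). Mir126a, an endothelial microRNA that overlaps an exon of Egfl7, held 6.79% ± 0.123 (SD, n = 2), and the cardiac Mir208b held 5.09% ± 0.131 (SD, n = 2). The 10 most abundant genes took 60.5% ± 0.328 (SD, n = 2) of the counts, and the first 20 took 76.9% ± 0.0085 (SD, n = 2).

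The other genes among the first 10 were Mir30e (32001 ± 2878 CPM), Mir26b (30050 ± 1131 CPM), Mir351 (28244 ± 4456 CPM) and Mir21a (28206 ± 209 CPM). Positions 11 to 20 were held by Mir17, Mirlet7g, Mirlet7i, Mir130a, Mir99b, Mir30a, Mir23a, Mir23b, Mir652 and Mir30d, from 23223 ± 1149 CPM for Mir17 to 10044 ± 649 CPM for Mir30d. The order of neighbours in this ranking was not always fixed, since Mir143 at 87662 CPM lay below Mir322 at 88188 CPM in replicate 1 and above it in replicate 2, at 89222 against 76342 CPM. Of 1973 genes in the tables, 712 had a count in either library, 586 had a count in both and 284 reached 10 CPM in both. At 1000 CPM or more in both libraries stood 77 genes, and 1261 genes had no count.

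On the mouse assembly GRCm38 with GENCODE M21, Mir335 (ENSMUSG00000065501.1) lies on chromosome 6 from 30741299 to 30741396 on the plus strand. Mir143 (ENSMUSG00000065445.2) lies on chromosome 18 from 61649196 to 61649258 on the minus strand, outside other annotated genes of that strand. Mir322 (ENSMUSG00000065418.1) lies on chromosome X from 53054255 to 53054349 on the minus strand. Mir99a (ENSMUSG00000065530.1) lies on chromosome 16 from 77598936 to 77599000 in an intron of Mir99ahg. Mir126a (ENSMUSG00000065540.1) lies on chromosome 2 from 26591357 to 26591429.

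**Figure D1:**
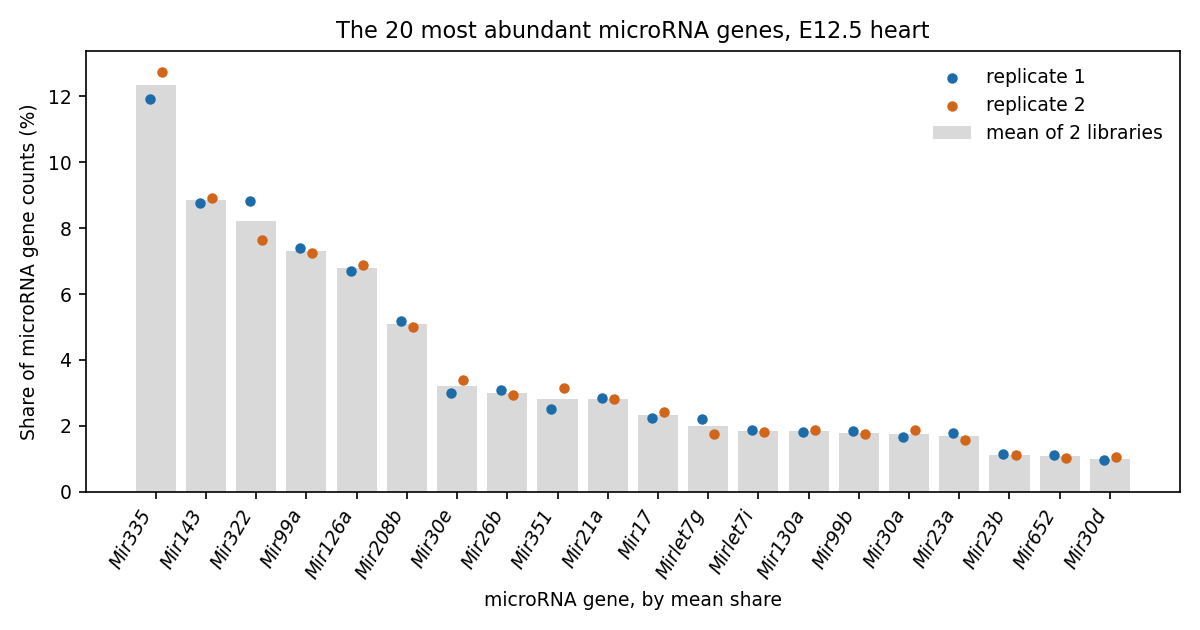
Share of microRNA gene counts (percent, vertical axis) for the 20 most abundant genes. Bars start at 0 and show the mean, points show each replicate, and Mir335 stands first in both replicates.

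The heart and skeletal muscle microRNAs took 6.30% ± 0.144 (SD, n = 2) of the counts, and 3 genes carried nearly all of this share. Each of the 3 lies in an intron of a myosin heavy chain gene. Mir208b, in Myh7, stood at 50918 ± 1313 CPM, Mir208a, in Myh6, at 9885 ± 160 CPM, and Mir499, in Myh7b, at 2138 ± 34.1 CPM. Within each library Mir208b exceeded Mir208a by a ratio of 5.15 ± 0.0497 (SD, n = 2) and Mir499 by a ratio of 23.8 ± 0.994 (SD, n = 2). Mir208a exceeded Mir499 by a ratio of 4.62 ± 0.149 (SD, n = 2). These ratios were many times their spread between replicates. That spread cannot show an error in the ratios that both libraries share.

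The remaining muscle microRNAs had few counts. Mir206, known from skeletal muscle, stood at 26.8 ± 3.12 CPM, and its neighbour Mir133b at 4.69 ± 1.27 CPM. Mir1a-1 had 11 and 25 counts in replicates 1 and 2 (3.60 ± 1.61 CPM), Mir133a-1 had 4 and 13 counts, Mir133a-2 had 2 and 8 counts, and Mir1b had 9 and 14 counts. A further 63 and 108 reads lay on the strand opposite to Mir1b, where GENCODE M21 places Mir1a-2, and were not counted to Mir1b. Mir133c had 0 counts in both libraries. The annotation holds further genes with the stems of Mir1a-1, Mir133a-1 and Mir133a-2, and reads that fit several places were not counted to any gene. The counts of these 3 genes therefore do not measure the total of the mature miR-1 and miR-133a. The list's share of 6.30% leaves out any such reads too, so its place among the lists is uncertain.

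Mir208b (ENSMUSG00000077928.1) lies on chromosome 14 from 54975700 to 54975776 and Mir208a (ENSMUSG00000065432.1) on the same chromosome from 54949060 to 54949142, both on the minus strand. Mir499 (ENSMUSG00000076312.1) lies on chromosome 2 from 155622880 to 155622958 on the plus strand. Mir1a-1 (ENSMUSG00000070144.1) lies on chromosome 2 from 180389048 to 180389124.

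Among microRNAs of other cell types, those of smooth muscle, fibroblasts and mesenchyme held the highest share, 12.2% ± 0.0958 (SD, n = 2), led by Mir143 and Mir21a. The endothelial list was measured through Mir126a alone. Epithelial microRNAs took 0.146% ± 0.00174 (SD, n = 2), with all 10 members at 10 CPM or more in both libraries and Mir429 highest at 433 ± 38.2 CPM, followed by Mir203 at 294 ± 14.9 CPM. Erythroid microRNAs took 0.142% ± 0.0617 (SD, n = 2), led by Mir451a, a microRNA of red blood cell precursors, at 1221 ± 638 CPM, with Mir144 at 148 ± 11.4 CPM. The liver and gut list took 0.0508% ± 0.0110 (SD, n = 2), with Mir215 at 272 ± 5.62 CPM and the hepatocyte microRNA Mir122 at 107 ± 105 CPM. White blood cell microRNAs took 0.0339% ± 0.00103 (SD, n = 2), with Mir223 at 160 ± 7.76 CPM and Mir155 at 156 ± 16.6 CPM. Reads opposite to Mir142b, where Mir142 is annotated, were left out of this share, which was 0.130% ± 0.00915 (SD, n = 2) with them. Neural and endocrine microRNAs held the lowest share, 0.0277% ± 0.000852 (SD, n = 2), led by Mir132, with 392 and 488 counts, and Mir128-1 at 60.4 ± 1.79 CPM. Of the 14 members analysed here, 9 have several copies, Mir128-1 among them, so their levels are uncertain, and the share was 0.0163% with single-copy genes only.

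Among families and genomic clusters, the mir-17-92 cluster and its paralogues, which are linked to proliferation, took 5.06% ± 0.218 (SD, n = 2), led by Mir17 and by Mir20a at 8792 ± 255 CPM. The imprinted Dlk1-Dio3 region took 4.93% ± 0.171 (SD, n = 2), and 42 of its 52 genes in the tables reached 10 CPM in both libraries, with Mir487b at 7466 ± 814 CPM and Mir411 at 6721 ± 319 CPM. The difference between these 2 lists was smaller than their spread between replicates. With opposite-strand counts given to the GENCODE M21 microRNA of that strand, the order turned, to 5.48% ± 0.156 (SD, n = 2) for the Dlk1-Dio3 list and 4.84% ± 0.226 (SD, n = 2) for the mir-17-92 list. The let-7 family, which accumulates as tissues mature, took 4.39% ± 0.429 (SD, n = 2), led by Mirlet7g at 19813 ± 3133 CPM and Mirlet7i at 18503 ± 462 CPM. With opposite-strand counts assigned, among them those of Mirlet7e, this share was 4.49% ± 0.418 (SD, n = 2). Of the 12 let-7 members analysed here, 5 have several copies, so their levels and the family's share are uncertain. The mir-17-92 list holds 4 such members of 15 and the Dlk1-Dio3 list 0, so the order of these lists may depend on copies. The pluripotency list took 0.547% ± 0.00246 (SD, n = 2), with Mir302a at 2189 ± 94.1 CPM and Mir302d at 1653 ± 11.5 CPM. MicroRNAs of the families of the Sfmbt2 intron cluster, taken by symbol wherever they lie, took 0.321% ± 0.0112 (SD, n = 2), with Mir467d and Mir467c, both in that intron, highest. Hairpins of both share a stretch of 22 bases with another microRNA hairpin, so their levels are uncertain. Of the 69 members of this list analysed here, 32 have several copies, so its share is uncertain as well. The list of Hox cluster microRNAs, which did not include Mir615, took 0.220% ± 0.0174 (SD, n = 2), with Mir10a at 1529 ± 19.4 CPM and Mir10b at 379 ± 122 CPM. The hypoxia-linked Mir210 stood at 964 ± 3.53 CPM, or 0.0964% of the counts.

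**Figure D2:**
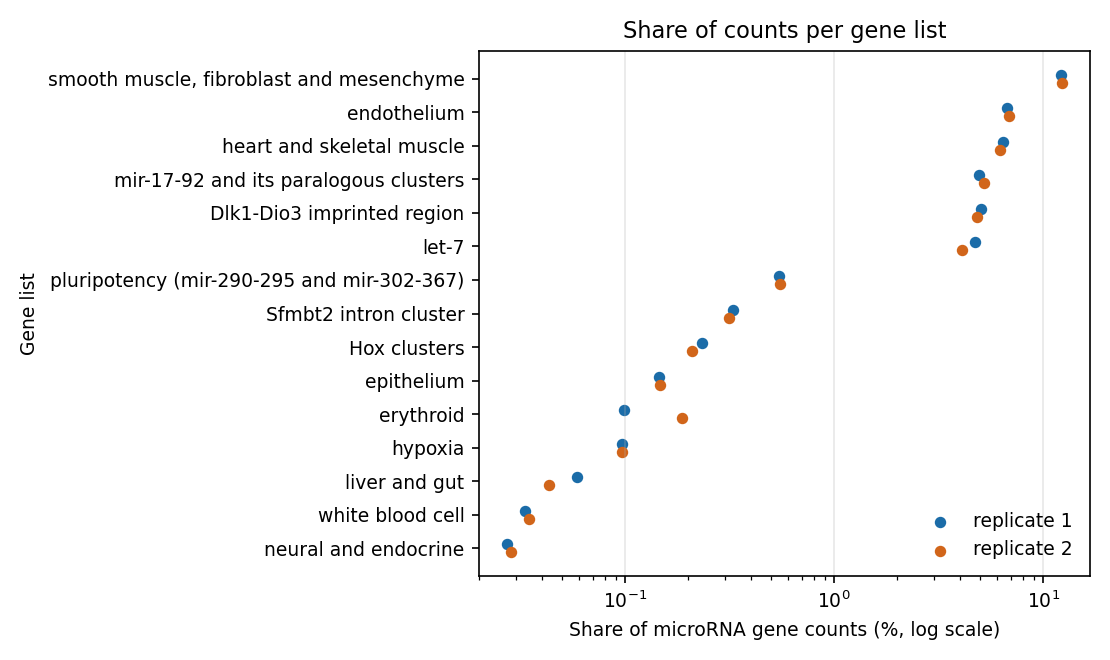
Share of microRNA gene counts per gene list (percent, log axis), with 1 point per replicate. The list of smooth muscle, fibroblast and mesenchyme microRNAs was highest at a mean of 12.2%, and the neural and endocrine list lowest at 0.0277%. Shares leave out reads that fit several places, so the order of lists whose members have several copies is uncertain.

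The 2 heart libraries gave closely matching profiles. Across 444 genes with at least 10 counts in total, log2(CPM + 1) of the 2 libraries had a Pearson r of 0.996 and a Spearman rho of 0.988, and 437 genes (98.4%) lay within 2-fold of each other. Genes are not independent replicates, so no p-value was given. The median absolute log2 difference was 0.17. The biological coefficient of variation, the spread between replicates beyond counting error, was 0.122, with a bootstrap SD over genes of 0.0189.

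Mir451a was higher in replicate 2 and Mir122 higher in replicate 1. Mir451a had 3447 counts (770 CPM) in replicate 1 and 8825 (1671 CPM) in replicate 2, a log2 ratio of 1.12 (ratio 2.17, 95% counting interval 2.09 to 2.26). Mir122 had 809 counts (181 CPM) and 171 counts (32.4 CPM), a log2 ratio of −2.44 (ratio 0.179, 95% counting interval 0.151 to 0.212). In an exact binomial test of the counts, 3 of 712 genes passed an adjusted p of 0.05 together with a 2-fold ratio. The third was Gm24187, named after its values were seen, with 13 and 2 counts (ratio 0.131, 95% counting interval 0.0143 to 0.577). The edgeR exact test with the common dispersion called 2 genes, Mir451a and Mir122, so the call of Gm24187 was lost, and the binomial test among genes with at least 10 counts in total called 4. The binomial test holds counting error alone and compares the 2 libraries, not conditions, so it does not show a difference beyond the spread between replicates. The edgeR exact test sets 1 library against 1, with a dispersion from these same libraries, so its calls do not show one either.

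Of the genes with at least 50 CPM that passed the exact binomial test at any ratio, the next highest in replicate 2 were Mir181b-2 (log2 ratio 0.58), Mir425 (0.55), Mir362 (0.55) and Mir30b (0.40). The next lowest in replicate 2 were Mir615 (−0.69), Mir10b (−0.67), Mir196b (−0.52) and Mir6236 (−0.43). Mir615, Mir10b and Mir196b lie within genes of the Hox clusters. Mir181b-2 has a second copy, so its level is uncertain. Without a minimum ratio, 118 genes passed, 57 higher and 61 lower in replicate 2, so that count includes small differences such as that of Mir143 (log2 ratio 0.03). In the erythroid list 1 gene passed with the 2-fold minimum over all genes tested and 1 adjusted over the list alone, and the liver and gut list gave the same counts. In the 13 other lists no gene passed either way.

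For 13 lists with at least 3 genes at 10 CPM, the median log2 ratio was set against 10000 random lists matched on expression. Outside the central 95% lay 4 lists, where 0.65 would lie outside if the genes of a list varied independently. Members of 1 cluster or family may vary together, so 4 against 0.65 does not show an excess. The Hox list, with 3 genes and without Mir615, had a median of −0.52 (percentile 0.05), while its member Mir10a had a log2 ratio of 0.03. The pluripotency list, with 8 genes, had a median of −0.22 (percentile 0.61), although 3 of its genes were higher in replicate 2. These were Mir302a, Mir302c and Mir302d, and the list's share did not fall, at 0.545% and 0.549% in replicates 1 and 2. The let-7 list, with 10 genes, had a median of −0.15 (percentile 1.86), and 0 of its genes were higher in replicate 2. The epithelial list, with 10 genes, had a median of 0.17 (percentile 98.7), and 7 of its genes were higher in replicate 2. These percentiles describe these 2 libraries and are not tests.

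**Figure D3:**
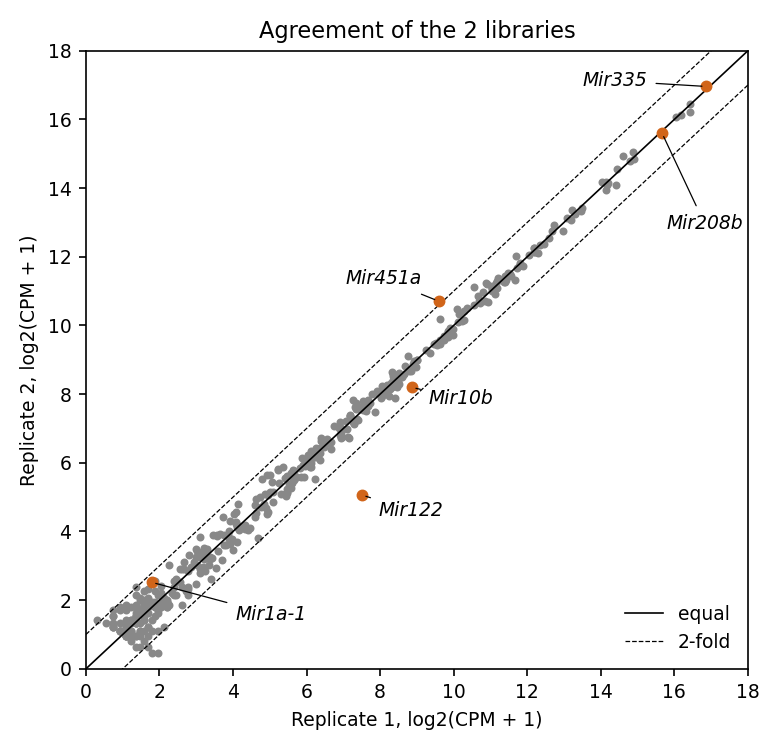
Level of each gene with at least 10 counts in total in replicate 1 (horizontal) and replicate 2 (vertical), as log2(CPM + 1). Solid and dashed lines mark equal levels and a 2-fold difference, and Mir451a lies above and Mir122 below the dashed lines.

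Members of 1 genomic cluster often stood at very different levels. Mir99a reached 73204 CPM while Mirlet7c-1 beside it had 46.6 CPM, and Mir30e reached 32001 CPM while Mir30c-1 had 65.1 CPM. In the cluster of Mir17, the lowest member was Mir19b-1 at 10.5 CPM. In the cluster on chromosome X led by Mir322, the lowest was Mir450-2 at 33.9 CPM. The mean level of genes with a second copy of the same name stem lay below that of the single-copy members of their own cluster in 15 of 15 clusters. The mean difference over clusters was −4.60 on the log2(CPM + 1) scale (p = 1e-05, two-sided permutation test within clusters, the smallest p the permutations can give). Single genes did not always follow the means. As examples chosen after their values were seen, the multi-copy Mir92-1, at 2394 CPM, lay above the single-copy Mir19a, at 49.0 CPM, and Mir92-2, at 44.6 CPM, above Mir18b, at 12.4 CPM. Reads that fit several places were not counted to genes.

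Some single-copy neighbours differed as well, as in Mir143 and Mir145a, at 88442 and 1204 CPM, a ratio of 73.7 ± 5.49 (SD, n = 2). In the cluster of Mir302a, Mir367 was lowest at 1.95 CPM. Over 35 clusters the mean difference between members was 3.69 log2 units against 4.29 when the same genes were reassigned at random (p = 0.0627, one-sided permutation test). With single-copy genes alone the difference was 2.97 against 4.05 (p = 0.0059, one-sided permutation test, 21 clusters). Across all genes with a count, the 655 single-copy genes had a median of 1.67 and the 57 multi-copy genes one of 4.27, a difference of −2.60 log2 units (p = 0.0113, two-sided permutation test). That direction reversed among genes with a mean of at least 10 CPM, to 2.499 (p = 0.00161, permutation test). The call was lost with shared 22-base windows as the definition, at −0.61 (p = 0.232, permutation test).

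**Figure D4:**
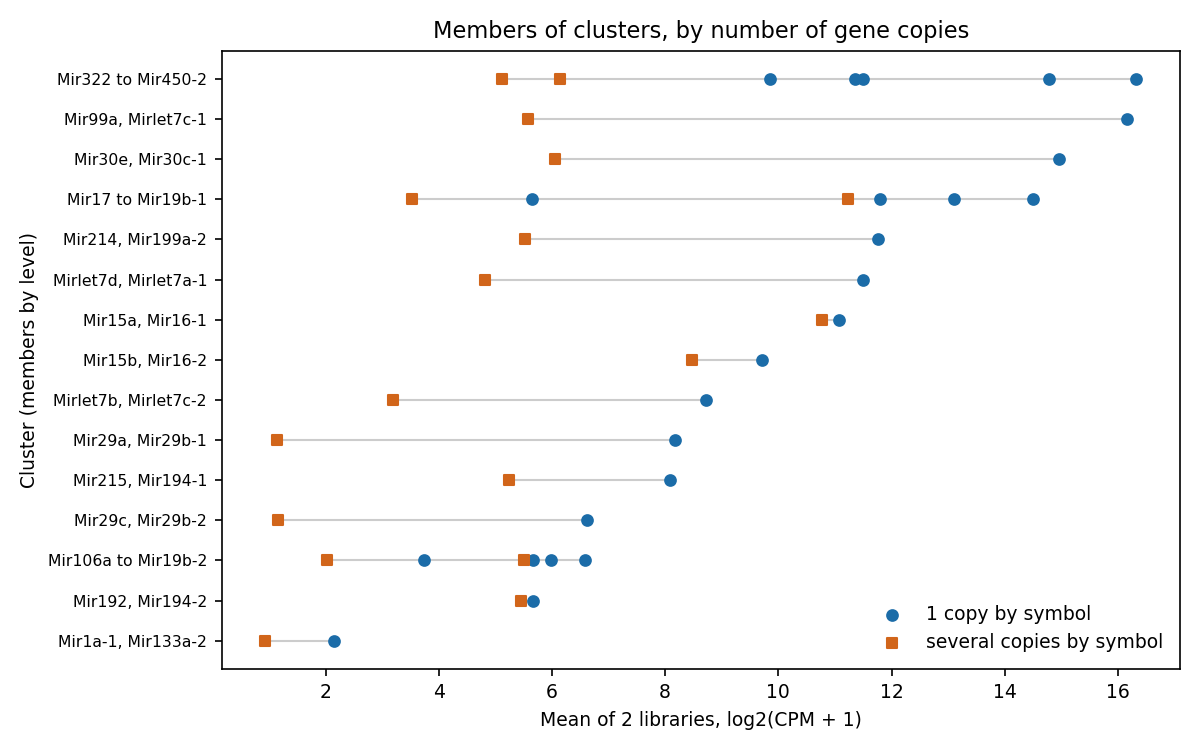
Level of the members of 15 genomic clusters, as the mean of log2(CPM + 1) over the 2 libraries, for genes with 1 copy (circles) and several copies (squares) by symbol among the genes analysed here, so that Mir1a-1 counts as 1 copy. The mean of the squares lies left of the mean of the circles in each of the 15 clusters.

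**Figure D5:**
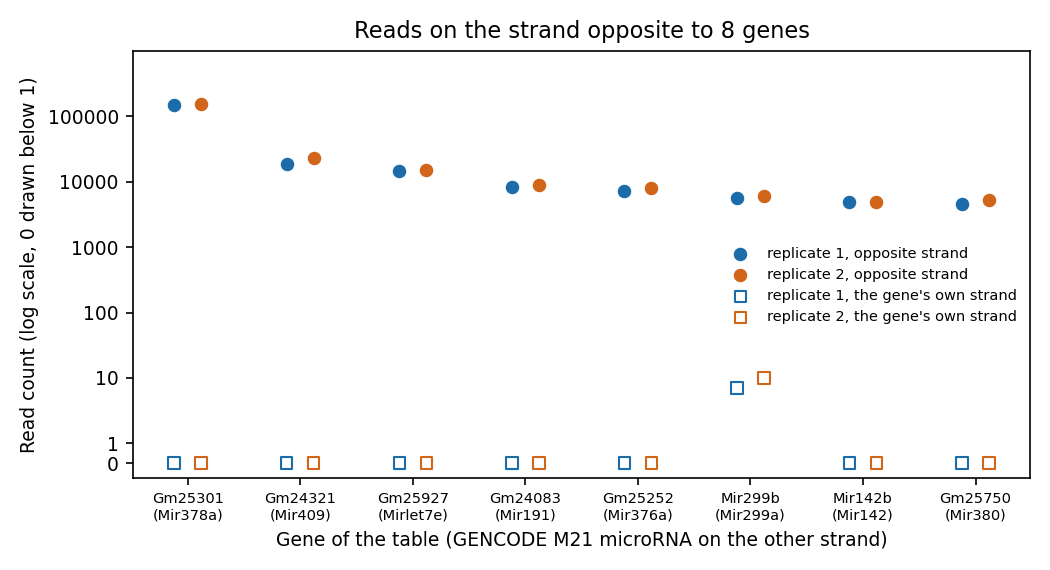
Read counts on the strand opposite to 8 genes (filled circles) and on the genes' own strand (open squares), per replicate, on a log axis with 0 drawn below 1, with the GENCODE M21 microRNA of that strand in brackets. Gm25301 had 150787 and 155088 reads on the opposite strand and 0 on its own.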

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

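The test of multi-copy genes within clusters was planned, and all other tests in this part, and the use of that one to weigh an explanation, were chosen only after the results were seen. Several kinds of reads lay outside the sense counts and stood above the limit of a count of 0. Antisense counts were 4.39% of the counts without regard to strand, reads that fit several places were 26.2% of all reads, and reads outside microRNA genes on either strand were 3.83% of all reads.

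Antisense counts above 3 in both libraries were found at 17 genes, and 15 of these have a GENCODE M21 microRNA on the opposite strand. As mean CPM of the sense total, the antisense level was 31521 at Gm25301 (opposite Mir378a), 4256 at Gm24321 (Mir409), 3055 at Gm25927 (Mirlet7e), 1764 at Gm24083 (Mir191) and 1562 at Gm25252 (Mir376a). It was 1200.3 at Mir299b (Mir299a), 1016 at Mir142b (Mir142), 1011 at Gm25750 (Mir380) and 399 at Mir497b (Mir497). Lower levels were 35.7 at Mir3074-1 (Mir24-1), 25.8 at Gm24111 (Mirlet7f-1), 17.3 at Mir1b (Mir1a-2), 7.75 at Mir486 (Mir3107), 5.19 at Mir126a (Mir126b) and 1.14 at Mir219a-1 (Mir219c). Mir203 at 6.65 and Mir708 at 4.42 have no such partner. In replicate 1 they had 35 antisense counts beside 1364 sense counts and 26 beside 1747.

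Loss of strand information in the libraries is argued against as the source of these reads. Summed over 139 genes with at least 1000 sense counts in both libraries, antisense counts were 0.00224 and 0.00176 per 100 sense counts in replicates 1 and 2, against 4.85 and 4.33 over all genes, although single genes such as Mir203 and Mir708 lay higher. A candidate explanation is a microRNA on the opposite strand that has no row of its own, since at least 99.95% of antisense counts in each library lay opposite such a microRNA. On that reading Mir378a would rank 8th, between Mir30e and Mir26b. No biological explanation was tested.

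The mean of multi-copy genes lay −4.60 log2 units from that of their single-copy cluster neighbours. Counting on the opposite strand is argued against, since antisense counts of these multi-copy genes were 0% of their shortfall. The omission of reads that fit several places is a candidate explanation. The counts these genes lacked to reach the mean of their neighbours, 786293 and 926086, were 31.4% and 34.6% of such reads in replicates 1 and 2. This is a weak check, since single-copy members of clusters also differed, by a mean of 2.97 log2 units. Reads that fit several places need not come from microRNA genes either. Differences in processing of the hairpins stay open, and the level of mature miR-1 and miR-133a cannot be read from these tables.

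Mir451a was 2.17-fold higher in replicate 2, and Mir122 was 5.58-fold higher in replicate 1. A joint rise of the erythroid list in replicate 2 is argued against, because Mir144 and Mir486 both lay over 2 spreads below 0.56. Mir144, the cluster neighbour of Mir451a, had a log2 ratio of −0.15 (spread 0.26). Mir486, chosen after its values were seen, had −0.36 (spread 0.28), and Mir3107 is annotated on its opposite strand. The spread joins counting error and the variation over genes of these same libraries. Whether Mir144 and Mir486 follow the number of red blood cells was not tested. Their values therefore do not decide whether replicate 2 held more red blood cells. More liver tissue in replicate 1 cannot be told apart from other sources for Mir122. The 4 other members of the liver and gut list had a median log2 ratio of −0.086, with single ratios from −0.16 to 0.38. The median of their single-gene spreads was 0.28, and their levels of 37.2 to 272 CPM could hide a small share. No other biological explanation was tested, since both libraries belong to 1 group, and a difference between the pools of embryos stays open.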

How the results depend on the processing

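The denominators that add reads fitting several places or give opposite-strand counts to their M21 microRNA, the definitions of copies by M21 stems and hairpin windows, and the ratios of genes were chosen after seeing the data. Of the main results, 18 values with a test kept their direction and side of the threshold, 46 without one stayed within the spread and 15 counts stayed within 1.5 times. Detected genes numbered 411 at 1 CPM, 254 over all reads and 176 at 100 CPM. The share of the 10 most abundant genes was 58.1% without regard to strand, 61.0% with single-copy genes and 57.5% without the top gene. Pearson's r was 0.997 without a filter, 0.995 with a pseudocount of 0.5 and 0.998 with 5, and rho was 0.922 without a filter and 0.993 with at least 100 counts. The coefficient of variation was 0.166 as the median over genes of the DESeq2 dispersion and 0.122 with DESeq2 size factors, and 118 genes differed between libraries with no minimum ratio, 4 with at least 10 counts and 2 by the edgeR exact test. The muscle share was 6.02% without regard to strand, 6.02% with opposite-strand counts assigned, 3.09% over all reads and 4.11% over sense counts plus reads that fit several places. Single-copy genes had the higher median at 10 CPM or more, 2.499 (p = 0.00161, permutation), and the lower at −0.61 (p = 0.232, permutation) with hairpin windows. Spread within clusters was 2.97 with single-copy genes (p = 0.0059, permutation). The denominator's size shows the cause for the shares over more reads, and the cause was not tested for the rest. Of other results, 194 levels and shares stayed within the spread and 72 moved beyond it. All 30 log2 ratios kept their direction and call, but their genes had been picked for the largest ratios that passed. All 65 list medians kept their side of the central 95% of random lists. The median of the white blood cell list went from 0.12 to 0.02 without regard to strand. The scalings were nearly equal, with TMM factors of 1.0004 and 0.9996 in replicates 1 and 2, so changing them could hardly alter a call. A change of scaling also shifts a list and its random lists almost alike. With 2 libraries, leaving out 1 cannot move a mean by more than the SD. Such values make up most of the 194 and many of the 46 that stayed within the spread. Those 2 counts therefore say little about how stable the results are. Comparisons between libraries have no value without a replicate. Windows shared in the genome were not run. Depth limits statements on genes with few counts.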

Other observations

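The sets in this part were chosen after the values were seen. The 5 microRNAs of the Mest, Igf2, H19 and Gnas loci took 13.4% ± 0.586 (SD, n = 2) of the counts, of which Mir335 was the largest part. Mir483, in an intron of Igf2, the gene of a fetal growth factor, stood at 4765 ± 110 CPM. Mir298 and Mir296, close together on chromosome 2 (174267504 to 174267585 and 174267047 to 174267125), stood at 2734 ± 33.2 and 2636 ± 141 CPM. Mir675, in an exon of H19, stood at 276 ± 1.75 CPM. Together with the Dlk1-Dio3 list these 57 genes took 18.3% ± 0.415 (SD, n = 2), and other imprinted loci, such as the Sfmbt2 intron, were not included.

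By sense counts, chromosome X carried the highest share of any chromosome, 14.04% ± 0.487 (SD, n = 2) from 120 genes, most of it from Mir322 and Mir351. Chromosome 6 held 12.5% ± 0.584 (SD, n = 2), nearly all from Mir335, and chromosome 14, which holds Mir208b, Mir208a and the cluster of Mir17, held 10.4% ± 0.0317 (SD, n = 2). Chromosome 18 held 8.99% ± 0.110 (SD, n = 2), without the reads opposite to Gm25301, where Mir378a is annotated on that chromosome. These reads, at 31521 CPM, would place it above chromosome 14. Chromosome Y had 0 counts in its 5 genes, which allows up to 0.670 and 0.568 CPM in replicates 1 and 2.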
